A study of Mus musculus with 6 samples.

How the data were processed

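Total RNA of splenic cDC2s from WT and CD11c-Cre Irf4fl/fl C57BL/6 mice was sequenced as Illumina libraries, per the labels' protocols. The authors deposited 1 table of raw counts per gene symbol, with whole numbers in 6 columns that the labels tie to 3 IRF4-deficient and 3 WT samples. Its counts had not been normalized, since the column totals differ and all values are whole. Per the submitters' processing notes, the tools were STAR, HTSeq and DESeq2, without versions, and the genome build was mm10. The annotation, the strand setting and the filter that left 14535 gene rows are not given in the sources used here. Without a known strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart. Counts of near-identical relatives, as in the MHC class I, Oas, Klr, Gbp, Pilr and Serpinb families, are uncertain where reads could be shared.

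WT columns carry numbers that differ from those in the sample titles, and were matched to the titles through the labels' source names. Replicates are named by the number in the title. Equal numbers are not said to mark a shared animal or day. The labels give no sort gate for the cDC2s, and the sample sheet numbers in their source names form a separate consecutive run for each genotype, so any effect of that order could not be separated from genotype. Table rows were unique by symbol, 7 were 0 in all libraries, and no row lacked a gene name. No column was left unused. Replicates of a group differed beyond counting noise, with a chi-square per degree of freedom of 7.68 to 16.1 over genes with at least 20 counts in a pair, so each library counted as 1 replicate.

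Locations come from GENCODE M21 on GRCm38, the assembly of mm10. Of the symbols, 13061 matched a single gene of that annotation and 1474 did not. Of the list members, 19 were matched through older symbols. The 18S, 5.8S and 28S precursor row (Rn45s) held 6.75 ± 1.30% of counts in IRF4-deficient and 8.12 ± 1.23% in WT libraries (SD, n = 3 each), and Malat1 1.89 ± 0.275% and 3.31 ± 0.491%.

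Genes were kept by edgeR's filterByExpr with the groups given, which left 11934. Library sizes were scaled by TMM, dispersions were estimated with robust shrinkage, and IRF4-deficient was tested against WT with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and "at least 2-fold" adds an absolute log2 fold change of 1 or more. Fold changes carry edgeR's prior count of 0.125, and the SE is derived from the quasi-likelihood F statistic. CPM values are TMM-scaled. The common biological coefficient of variation was 0.156. Intervals on count ratios are exact binomial intervals at the 95% level over group totals and cover counting error only.

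The design, the alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. The lists cover dendritic cell subsets and functions, general programmes and markers of other cell types. Those with at least 3 tested members were tested with camera in limma 3.58.1, two-sided, with a preset correlation of 0.01, and adjusted over the 32 lists. Beside it stand camera with an estimated correlation and fry. The former rests on the 4 residual degrees of freedom of these libraries, so few lists can pass it and a failure decides little. Named are Irf4, the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap and whose mean CPM was at least 5, and up to 4 members per list with the smallest p. Predicted and clone-named gene models and immunoglobulin and T cell receptor segments were left out of the largest changes. Any list member with a mean of at least 50 CPM could be named as well. Some genes that were tested and are part of the list counts are not reported here by name. Genes outside this rule are named only where a count of 5 or fewer is spelled out or in the closing section, and were then chosen after their values were seen. Among the list genes these are Ctsl and Snx22, and outside the lists Malat1.

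Alternatives were DESeq2 1.42.0, DESeq2 size factors and upper-quartile factors in edgeR, no filter, a filter of 5 CPM in 3 libraries, limma-voom, no robust shrinkage, the replicate number as a block, removal of haemoglobin and receptor segment genes (which removed 1 row, Beta-s), and leaving out each library. Removal of Rn45s and Malat1, and a covariate built from 12 red pulp macrophage genes, were added after seeing the data. The edgeR steps were tested on simulated data with counts drawn from these libraries' means and sizes and 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. Of these, 32.8%, 80.6% and 98.5% were recovered among 11808 tested genes, with 13 false calls among 154. Changes near 1.5-fold were therefore often missed in data simulated this way. The real fit called 2429 genes, which makes its adjusted threshold less strict, so these shares do not carry over to it.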

Results

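Gene expression was measured by RNA-seq in type 2 conventional dendritic cells (cDC2s) from mouse spleen, antigen-presenting cells that express the transcription factor IRF4. The series holds 3 wild-type (WT) libraries and 3 libraries from CD11c-Cre Irf4fl/fl mice, in which Cre recombinase under the CD11c (Itgax) promoter deletes the loxP-flanked part of Irf4 in CD11c-expressing cells. The latter are called IRF4-deficient here. All mice were of the C57BL/6 strain per the labels. The deposited table gave raw counts for 14535 genes, with totals of 10609420, 7949462 and 8672683 in IRF4-deficient replicates 1 to 3 and 7445637, 11459920 and 7421605 in WT replicates 1 to 3. Between 13772 and 14043 genes had a count in each library. The labels do not say whether replicates came from separate mice, so the p-values measure the spread between these libraries, which may be technical. The design names 1 comparison, IRF4-deficient against WT, which asks how the cDC2 transcriptome differs when Irf4 is deleted. The Cre transgene and the floxed allele go with the deletion. No group carries Cre alone, so their effects cannot be separated from loss of Irf4.

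Irf4 fell in the IRF4-deficient cDC2s, from 310.9 ± 29.6 to 80.01 ± 13.2 CPM (counts scaled to a common library size with TMM factors, mean ± SD, n = 3 each), a 3.88-fold lower level. Dendritic cell maturation genes, interferon-induced genes and MHC genes were lower more often than higher, as with Ccr7 (8.09-fold lower) and Oasl2 (2.92-fold lower). Genes typical of monocytes, macrophages and the ESAM-low cDC2 subset were higher more often than lower, as with Cx3cr1 (4.21-fold) and Lyz2 (2.23-fold). Irf8, the IRF family member central to type 1 conventional dendritic cells (cDC1s), rose 2.67-fold, from 47.7 ± 7.44 to 127.0 ± 17.2 CPM. In all, 2429 of 11934 tested genes were called by edgeR at an adjusted p under 0.05, 1178 higher and 1251 lower in IRF4-deficient cells, and 881 of them differed at least 2-fold.

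As the targeted gene, Irf4 (GRCm38 chromosome 13, 30749226 to 30766976, plus strand, 9 exons in its first annotated transcript) checks the labels. Its level was 90.8, 65.3 and 84.0 CPM in IRF4-deficient replicates 1 to 3, and 291.8, 295.8 and 345.0 CPM in WT replicates 1 to 3, so each library matched its label. The log2 fold change was -1.95 with a standard error (SE) of 0.12 (edgeR adjusted p = 1.45e-09), which left 25.8% of the WT level (95% interval 22 to 30.3%). The labels do not say which exons are deleted, and the counts per gene cover whole genes, so reads from exons outside the deleted part count toward this remainder. Of the 9 tested IRF genes, 1 (Irf8) was called higher and 4 lower, the same counts as when adjusted over the list alone. The targeted Irf4 itself is among those called lower. Irf5 and Irf1 fell with log2 fold changes of -0.47 (SE 0.10) and -0.56 (SE 0.14), of which Irf1 went to -0.10 with the red pulp index as a covariate (an index of 12 red pulp macrophage genes, added after seeing the data) and was no longer called (adjusted p 0.861). Irf9 (-0.31, SE 0.10) had an edgeR adjusted p of 0.0288, which was 0.151, 0.103, 0.0706 and 0.0524 without IRF4-deficient replicate 2 and WT replicates 1, 2 and 3. Irf2, at 168 and 145 CPM in IRF4-deficient and WT cells, was not called. The camera adjusted p of the family was 0.111, and 0.049 without WT replicate 3, with a range of 0.049 to 0.49 over the alternatives that use camera, while fry gave an adjusted p of 0.0208. These tests include the deleted gene Irf4, so their downward direction is in part fixed by the design.

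**Figure D1:**
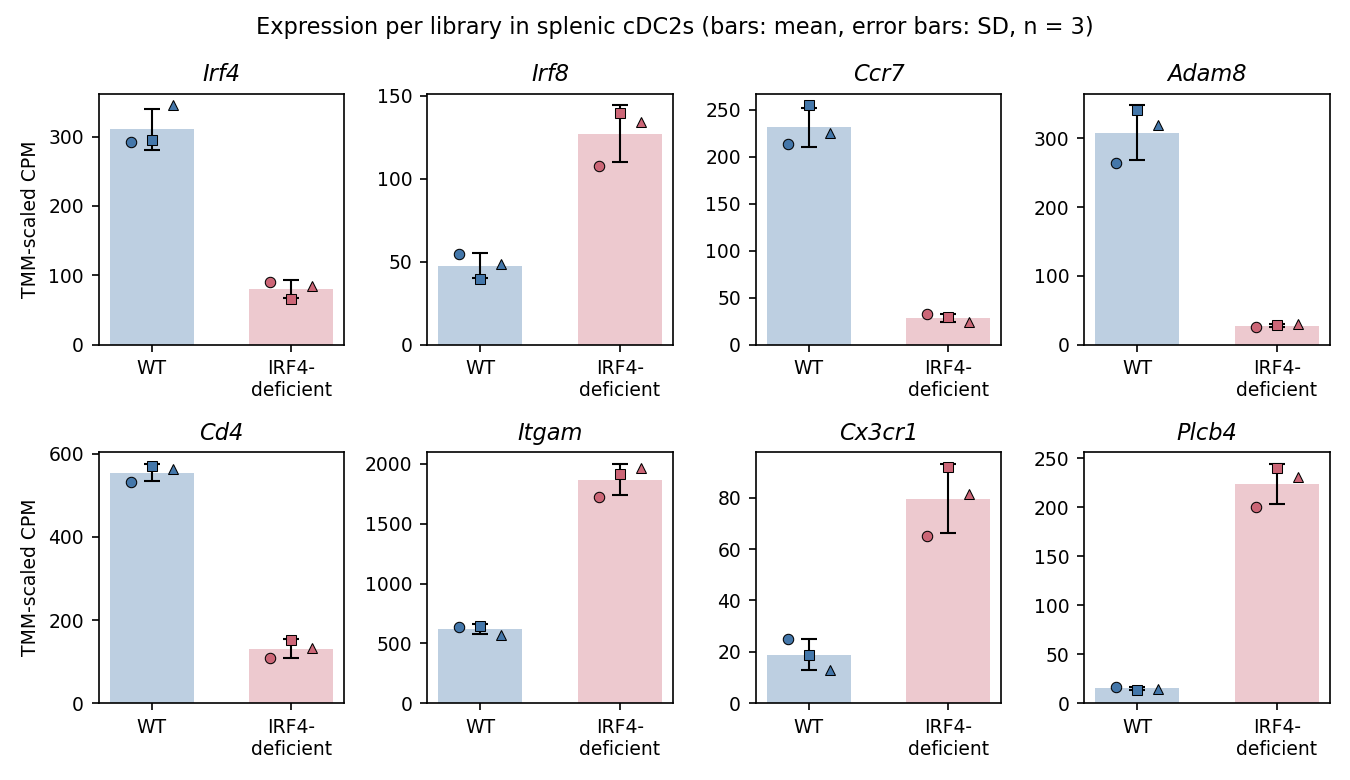
TMM-scaled CPM (vertical axes, linear from 0) of 8 genes in the 3 WT libraries (blue) and the 3 IRF4-deficient libraries (red), with points for libraries (circle, square and triangle for replicates 1, 2 and 3), bars for means and error bars for SD. In each panel the 3 libraries of one genotype lie apart from the 3 of the other, as for Irf4 with 65.3 to 90.8 CPM against 291.8 to 345.0 CPM.

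The largest increases by the fixed rule were in Syt6, Gata3, Plcb1, F5, Fndc1, Vegfc, Sidt1, Siglec5 (an older symbol of Siglecf), Plcb4, Ifitm1, Dbn1 and Fat2. Among those with a substantial count, Plcb4, a phospholipase C beta isoform that signals below G protein-coupled receptors, rose 14.9-fold from 15.01 ± 1.43 to 223.5 ± 20.4 CPM. Its relative Plcb1 rose 38.7-fold (log2 fold change 5.28, SE 0.20). Both genes lie on the plus strand of chromosome 2, Plcb1 at 134786067 to 135475258 and Plcb4 at 135659011 to 136014593. Ifitm1, an interferon-induced transmembrane protein gene, rose 14.9-fold to 374.5 ± 28.3 CPM (log2 fold change 3.90, SE 0.11). Vegfc, a lymphatic growth factor gene, rose 19.3-fold to 35.04 ± 10.8 CPM. Some of these genes were nearly silent in WT. Syt6 had 5 counts in the 3 WT libraries together and 438 in the IRF4-deficient ones, a depth-scaled ratio of 80.1 with a 95% counting interval of 34.1 to 248. Gata3, known as a T helper and innate lymphoid cell regulator, had 9 and 505 counts, a ratio of 51.3 (26.8 to 113).

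The largest decreases were in Serpinb2, Kif17, Pla2g4f, Fndc5, Cygb, Socs2, Adam8, Apof, Nudt17, Mmp12, Rasgrp3 and Nr4a3. Adam8, a membrane metalloprotease gene (chromosome 7, 139978932 to 139992562), fell 11.1-fold from 308.6 ± 39.4 to 27.9 ± 2.24 CPM (log2 fold change -3.47, SE 0.12). Rasgrp3, an exchange factor for Ras-type GTPases, fell 9.59-fold from 353.1 ± 19.8 to 36.8 ± 8.55 CPM. Mmp12, the macrophage elastase gene, went from 248.8 ± 31.4 to 24.9 ± 6.68 CPM. Socs2, a suppressor of cytokine signalling, went from 56.0 ± 5.95 to 4.91 ± 1.54 CPM, and Serpinb2 from 21.2 ± 4.04 to 1.21 ± 1.12 CPM. These 24 genes were called in each of the 6 fits that left out 1 library.

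**Figure D2:**
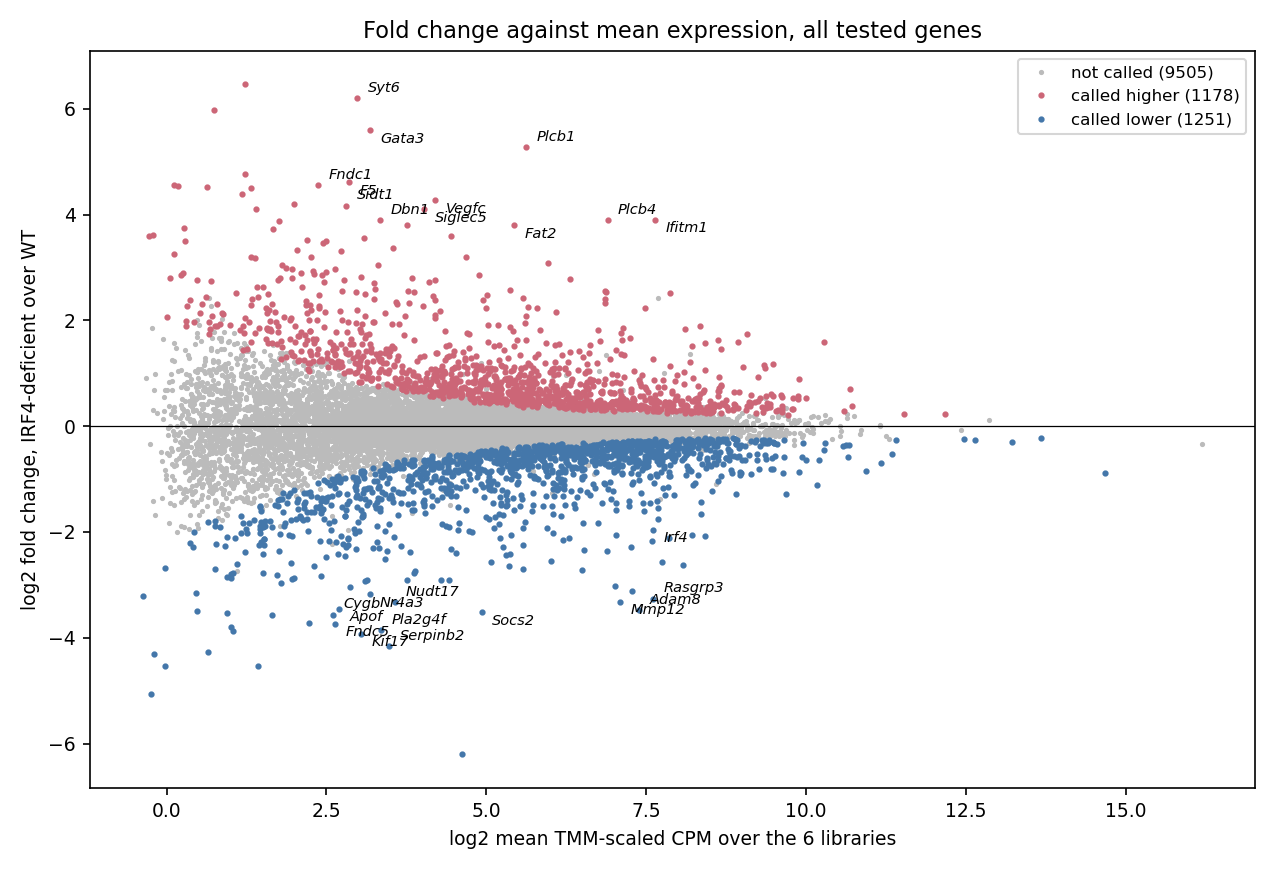
Log2 fold change of IRF4-deficient over WT (vertical axis) against log2 mean TMM-scaled CPM over the 6 libraries (horizontal axis), 1 point per tested gene. Red points are the 1178 genes called higher, blue points the 1251 called lower and grey points the remaining ones, with Irf4 and the 24 largest named changes labelled in italics.

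Of 29 tested members of the mature dendritic cell programme 21 were called lower and 1 higher (23 and 1 adjusted over the list alone), with a median log2 fold change of -0.95. The list test gave camera adjusted p = 1.89e-19 with a preset correlation and adjusted p = 0.476 with an estimated correlation. Ccr7, the receptor that guides mature dendritic cells to lymph nodes (chromosome 11, 99144196 to 99155077), fell from 231.1 ± 20.96 to 28.5 ± 4.31 CPM (edgeR adjusted p = 3.88e-12). Fscn1, an actin-bundling protein gene, fell 5.04-fold and Adam23 2.44-fold. The costimulatory ligand gene Cd80 fell with a log2 fold change of -0.68 (SE 0.11), while Cd86, at 111 CPM in IRF4-deficient and 110 CPM in WT cells, and Relb, at 184 and 181 CPM, were not called. Cd274, the PD-L1 gene, was the member called higher (edgeR adjusted p = 0.041), but not in 4 of the 6 fits that left out 1 library, those without IRF4-deficient replicates 1 and 3 and WT replicates 1 and 2 (adjusted p 0.0838, 0.139, 0.174 and 0.102), nor without robust shrinkage (0.0555).

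Of 35 tested interferon-induced genes 21 were called lower and 1 higher (21 and 2 adjusted over the list alone), with a median log2 fold change of -0.66. The camera adjusted p was 5.53e-13, and adjusted p = 0.476 with an estimated correlation. Oasl2 fell from 305.6 ± 42.5 to 104.9 ± 5.17 CPM, and Usp18, a negative regulator of interferon receptor signalling, fell 3.24-fold. Mx1 fell 2.32-fold. Oas3 was the member called higher. Slfn5 (379 and 388 CPM in IRF4-deficient and WT cells) and Ddx58 (142 CPM in both) were not called.

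Antigen presentation genes were called lower more often than higher. Camera gave adjusted p = 0.000339 for class I and 0.00206 for class II, and for both adjusted p = 0.49 with an estimated correlation. In the MHC class I list 12 of 18 tested members were called lower and 0 higher (13 and 0 adjusted over the list alone), led by Nlrc5, the transactivator of class I genes, which fell 2.11-fold. Tap1, a subunit of the peptide transporter, fell 1.57-fold, while B2m (7780 and 7170 CPM) was not called. In the MHC class II list 12 of 22 were called lower and 2 higher (14 and 3 adjusted over the list alone). H2-Eb2 fell 2.40-fold and H2-Ob, which restrains peptide loading, 1.86-fold, while the abundant H2-Aa fell 1.23-fold. The lysosomal protease genes Lgmn and Ctsl were the members called higher, with an edgeR adjusted p for Ctsl of 0.00934 and of 0.0546 without WT replicate 3. The number of class II genes called lower was 7 without WT replicate 2.

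Monocyte and macrophage markers were higher more often than lower, with 12 of 26 tested members called higher and 1 lower (19 and 1 adjusted over the list alone) and a median log2 fold change of 0.95. Lyz2, the lysozyme gene, rose from 402.4 ± 58.3 to 897.3 ± 75.6 CPM. Treml4 rose 3.19-fold and Csf1r, the receptor for macrophage colony-stimulating factor, 2.16-fold. Emr1, the F4/80 gene, was the member called lower (log2 fold change -0.61, SE 0.09). In the ESAM-low cDC2 list 10 of 17 were called higher and 3 lower (10 and 3 adjusted over the list alone), and 5 of the tested genes are also in the monocyte list. Cx3cr1, the fractalkine receptor gene, rose from 18.9 ± 6.03 to 79.6 ± 13.5 CPM and Ccr2 3.07-fold, while Cd209a fell 2.48-fold. Camera gave adjusted p = 7.77e-08 for the monocyte list and 0.000373 for the ESAM-low list, and for both adjusted p = 0.49 with an estimated correlation. With the red pulp index as a covariate 4 and 5 members of these lists were called higher and camera gave adjusted p of 0.274 and 0.187. Over all alternatives the adjusted p ranged from 2.06e-17 to 0.49 and from 4.67e-06 to 0.49.

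Within the monocyte and macrophage list, genes typical of red pulp macrophages of the spleen differed between the IRF4-deficient libraries. Vcam1 stood at 664.3, 924.4 and 1106 CPM in IRF4-deficient replicates 1, 2 and 3 against 344.1 to 521.6 CPM in WT. It was called (edgeR adjusted p = 0.031), but not without IRF4-deficient replicates 2 or 3 or WT replicate 1 (adjusted p 0.0943, 0.0662 and 0.135), nor with no filter (0.0546). Hmox1 stood at 258.2, 402.5 and 601.3 CPM against 141.9 to 190.0 CPM and was not called (edgeR adjusted p = 0.064), but was by DESeq2 (0.00163) and limma-voom (0.000563), and in edgeR without robust shrinkage (0.000127), with the replicate block (0.0488) and without IRF4-deficient replicate 1 (4.34e-05) or 3 (0.0179). Lyz2 stood at 878.8, 980.4 and 832.6 CPM in the same libraries. IRF4-deficient replicate 3 lay apart from replicates 1 and 2 on the second principal component (14% of the variance), while the first (56.8%) separated the genotypes. Without IRF4-deficient replicate 3, 2431 genes were called.

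**Figure D3:**
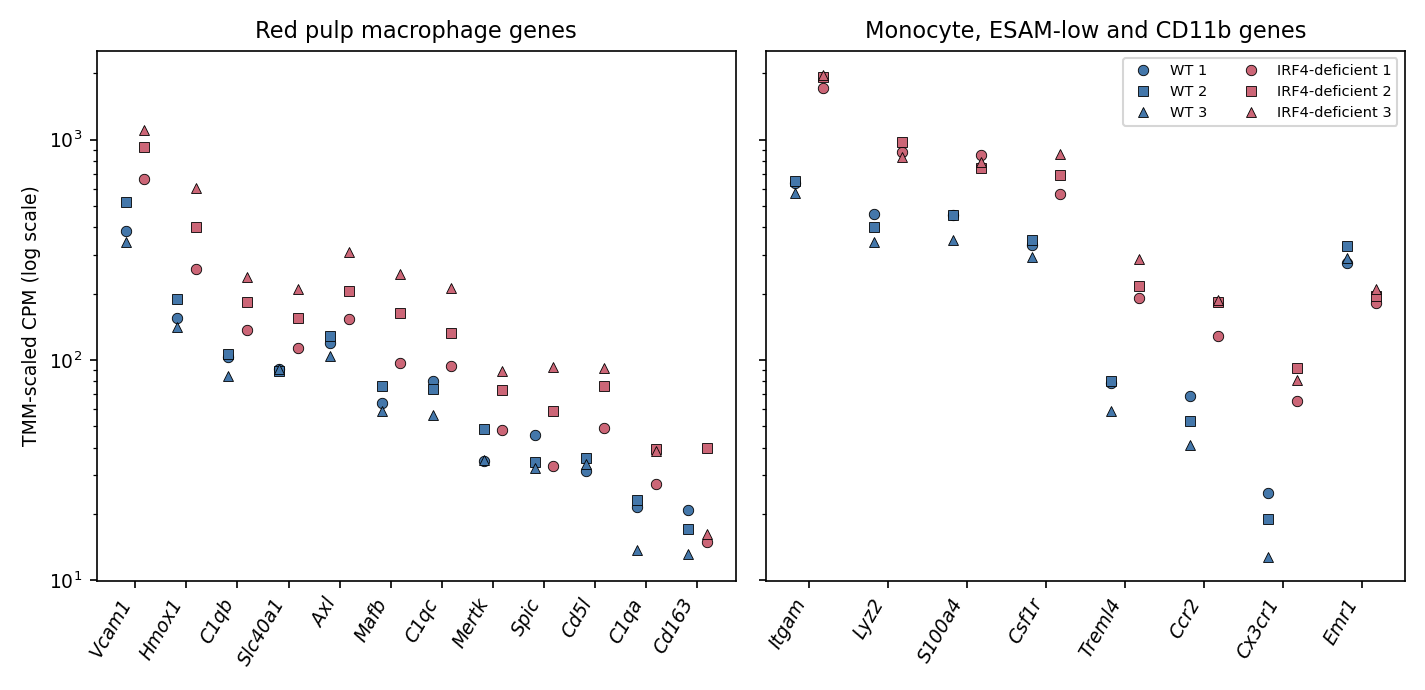
TMM-scaled CPM on a log axis for the 12 red pulp macrophage genes of the index (left panel) and 8 monocyte, ESAM-low and CD11b genes (right panel), with WT libraries in blue, IRF4-deficient ones in red, and circle, square and triangle for replicates 1, 2 and 3. For 10 of the 12 genes in the left panel the triangle lies highest among the IRF4-deficient libraries, as for Hmox1 with 601.3 CPM, while for Lyz2 it lies lowest with 832.6 CPM.

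Lectin, Fc and scavenger receptor genes were higher more often than lower, 12 against 3 of 31 tested (13 and 3 adjusted over the list alone). Clec4a3 rose 3.41-fold from 62.4 ± 14.6 to 212.6 ± 19.7 CPM and Cd33 2.93-fold. Ly75, the DEC-205 gene, fell 3.51-fold. Of the tested members 6 are also in the ESAM-low list and 8 in the cDC2 surface marker list. The camera adjusted p was 0.00293, and adjusted p = 0.588 with an estimated correlation. With the red pulp index as a covariate 2 members were called higher and camera gave an adjusted p of 0.935 (range over its alternatives 8.56e-06 to 0.935).

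cDC1 marker genes went both ways, 10 of 18 called higher and 3 lower (10 and 3 adjusted over the list alone; camera adjusted p = 0.124, and 0.027 without IRF4-deficient replicate 1, within a range of 0.027 to 0.655 over its alternatives). With the red pulp index as a covariate 2 were called higher and 2 lower. Besides Irf8, Ifi205 rose 3.34-fold, Clec9a 1.70-fold from 47.8 ± 7.70 to 81.8 ± 17.7 CPM, and Tlr3 with a log2 fold change of 0.86 (SE 0.13). Batf3, a transcription factor required for cDC1 development, fell 2.46-fold from 66.3 ± 1.62 to 26.9 ± 1.49 CPM. Wdfy4, which cDC1s use for cross-presentation, fell 2.15-fold from 1577 ± 70.3 to 732.0 ± 40.1 CPM. Snx22 was also called lower.

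Surface markers of cDC2s changed in both directions, 6 higher and 8 lower of 24 (the same adjusted over the list alone; camera adjusted p = 0.552). Itgam, the CD11b gene (chromosome 7, 128062640 to 128118491), rose 3.03-fold from 617.3 ± 41.5 to 1869 ± 131 CPM. Cd4 (chromosome 6, 124864692 to 124888221) fell 4.23-fold from 554.8 ± 20.6 to 131.3 ± 21.9 CPM. The cytokine receptor genes Flt3, Csf2rb and Kit fell, with log2 fold changes of -0.72 (SE 0.08), -0.95 (SE 0.09) and -0.63 (SE 0.09). Sirpa, at 981 and 909 CPM, was not called. In the ESAM-high list 6 of 17 were called higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.584). Epcam rose 5.61-fold and Adam23 was called lower, while Dtx1 (196 and 210 CPM) was not called. For the ESAM-high and surface marker lists the median log2 fold change (0.024 and 0.069) and the mean (-0.115 and -0.059) differed in sign.

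Among dendritic cell transcription factors 11 of 42 were called higher and 10 lower (15 and 10 adjusted over the list alone; camera adjusted p = 0.656). The targeted Irf4 is among the lower ones. Klf4, required by part of the cDC2s, rose 2.09-fold and Klf2 1.95-fold. Zbtb46, which marks conventional dendritic cells, fell 1.92-fold and Rbpj, the Notch cofactor, with a log2 fold change of -0.85 (SE 0.13). Of 28 pattern recognition receptor genes 8 were called higher and 10 lower (9 and 10 adjusted over the list alone; camera adjusted p = 0.796, direction down beside a median log2 fold change of 0.006 and a mean of 0.02). Tlr5, the flagellin receptor gene, rose 2.60-fold and Tlr11 fell 4.43-fold, while Tlr9 stood at 281 and 280 CPM. Of 27 migration and chemokine genes 8 were called higher and 5 lower (10 and 5 adjusted over the list alone; camera adjusted p = 0.77), with Ccr6 higher and Cxcl16 and Ccl5 lower. Of 17 cytokine genes 3 were called higher and 5 lower (3 and 6 adjusted over the list alone; camera adjusted p = 0.584). Vegfa rose 7.27-fold to 51.9 ± 4.91 CPM and Il1rn 3.49-fold, while Ebi3 fell 2.38-fold and Il1b 1.66-fold. Of 18 costimulation and checkpoint ligand genes 5 were called higher and 3 lower (the same adjusted over the list alone; camera adjusted p = 0.966), with a median log2 fold change of -0.056 and a mean of 0.199, and without WT replicate 2 the number called higher was 3.

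Among cell cycle genes 17 of 37 were called higher and 0 lower (20 and 0 adjusted over the list alone). Mki67 rose 1.45-fold from 722.3 ± 8.34 to 1048 ± 99.1 CPM, Mcm5, part of the replicative helicase, 1.98-fold and Top2a 1.48-fold. Without WT replicate 2 the number called higher was 11. The camera adjusted p was 3.63e-06, and adjusted p = 0.588 with an estimated correlation. Immediate early and stress genes had 0 called higher and 5 lower of 29 (the same adjusted over the list alone; camera adjusted p = 0.124). In this list WT replicate 3 lay apart, with Egr1 at 71.98 CPM against 833.8 and 672.3 CPM in WT replicates 1 and 2 and 224.1 to 282.6 CPM in the IRF4-deficient libraries. Egr1 was not called (edgeR adjusted p = 0.512), but was lower without that library (4.15e-08). Without WT replicate 3, 15 members were called lower and the camera adjusted p was 1.66e-09, the lowest of a range up to 0.799 over its alternatives.

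Metabolic and housekeeping lists did not pass camera's threshold. Glycolysis genes had 3 higher and 3 lower of 19 (4 and 3 adjusted over the list alone; camera adjusted p = 0.546; 0 to 4 higher in fits without 1 library), with the glucose transporter gene Slc2a3 (log2 fold change -1.45, SE 0.12) and the regulatory enzyme gene Pfkfb3 (-1.29, SE 0.10) lower. Cholesterol and sterol genes had 2 higher and 3 lower of 28 (the same adjusted over the list alone; camera adjusted p = 0.77), with Abca1 higher and Srebf2 lower, of which neither was called with the red pulp index as a covariate (log2 fold change 1.07, then 0.26, and -0.44, then -0.34; adjusted p 0.711 and 0.258). ER chaperone genes had 0 higher and 4 lower of 22 (the same adjusted over the list alone; camera adjusted p = 0.504), with the chaperone cofactor gene Sdf2l1 lower (log2 fold change -0.70, SE 0.15). Apoptosis regulators had 2 higher and 3 lower of 25 (the same adjusted over the list alone; camera adjusted p = 0.339, while fry gave an adjusted p of 0.028, direction down), with Casp8 higher and Mcl1 lower.

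Markers of other cell types were measured as a check of the sorted cells, for which the labels give no sort gate. Only differences between genotypes were tested, so other cells present alike in both groups would not show. Many markers were absent from the count table, which held 9 of 15 plasma cell, 11 of 17 neutrophil and 7 of 16 stromal and endothelial ones. Of receptor segment and haemoglobin genes only Beta-s was found. These gaps limit the check. Plasmacytoid dendritic cell markers had 5 higher and 4 lower of 16 (7 and 4 adjusted over the list alone; camera adjusted p = 0.0404, and adjusted p = 0.5 with an estimated correlation). Atp1b1 and Runx2 were higher and Tlr7 and Ccr9 lower. T cell markers had 4 higher and 0 lower of 14 (5 and 0 adjusted over the list alone; camera adjusted p = 0.0404, and adjusted p = 0.49 with an estimated correlation), with Cd6 and Il7r higher. Without IRF4-deficient replicate 3 neither list passed, with camera adjusted p of 0.147 and 0.141, and without WT replicate 2 with 0.0866 and 0.0724. With the red pulp index as a covariate they had 0.18 and 0.391, and the plasmacytoid list had 0.137 with the stricter filter. The ranges over their alternatives were 0.0195 to 0.5 and 0.0112 to 0.49. Erythroid and platelet markers had 2 higher and 0 lower of 7 (2 and 1 adjusted over the list alone), Itgb3, an integrin gene, 5.31-fold and Car2. Here camera and the mean log2 fold change (0.148) pointed up and the median (-0.393) down. The camera adjusted p was 0.0362, then 0.104 without IRF4-deficient replicate 2, 0.0766 without WT replicate 2, 0.0853 with no filter, 0.292 with the index as a covariate, and adjusted p = 0.49 with an estimated correlation, within a range of 0.0104 to 0.49.

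B cell markers had 1 higher and 4 lower of 16 (the same adjusted over the list alone; camera adjusted p = 0.224, and 0.0314 without WT replicate 2, within a range of 0.0314 to 0.935), with Cr2 lower. Mast cell, basophil and eosinophil markers had 3 higher and 2 lower of 6 (4 and 2 adjusted over the list alone; camera adjusted p = 0.127), Siglec5 and Ccr3 among the higher ones and Kit among the lower. Neutrophil markers had 2 higher and 1 lower of 4 (the same adjusted over the list alone; camera adjusted p = 0.124, and 0.0251 without WT replicate 1, within a range of 0.0251 to 0.838), with Mmp9 and Csf3r higher. NK cell markers had 2 higher and 1 lower of 7, plasma cell markers 1 and 1 of 5, and stromal and endothelial markers 0 and 0 of 5, with the same counts adjusted over the list alone and camera adjusted p of 0.951, 0.951 and 0.552. Of the stromal and endothelial markers 3 had an unadjusted p under 0.05 by edgeR. The plasma cell list pointed up by camera beside a median log2 fold change of -0.036 and a mean of -0.051. Xist made up 0.593 ± 0.052% of counts in IRF4-deficient and 0.676 ± 0.069% in WT libraries (n = 3 each) and was the 1 of 4 tested sex genes called, with 0 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.673). Its edgeR adjusted p was 0.0279, and 0.12, 0.0885, 0.0986 and 0.12 without IRF4-deficient replicates 1 and 3 and WT replicates 2 and 3. Xist stood at 5785 CPM in IRF4-deficient and 6949 CPM in WT cells. The Y chromosome genes Ddx3y, Kdm5d and Eif2s3y stood at 2.91, 2.27 and 1.49 CPM, and at 3.77, 2.33 and 1.49 CPM in WT. Thus Xist was high and these genes were low in both genotypes. Malat1, a nuclear noncoding RNA, made up 1.89 ± 0.275% and 3.31 ± 0.491% of counts and was called lower (edgeR adjusted p = 0.00145). The list of mitochondrially encoded genes had 0 members in the table. In total 72 of the 540 tested list genes belong to more than 1 list, so the lists are not independent.

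**Figure D4:**
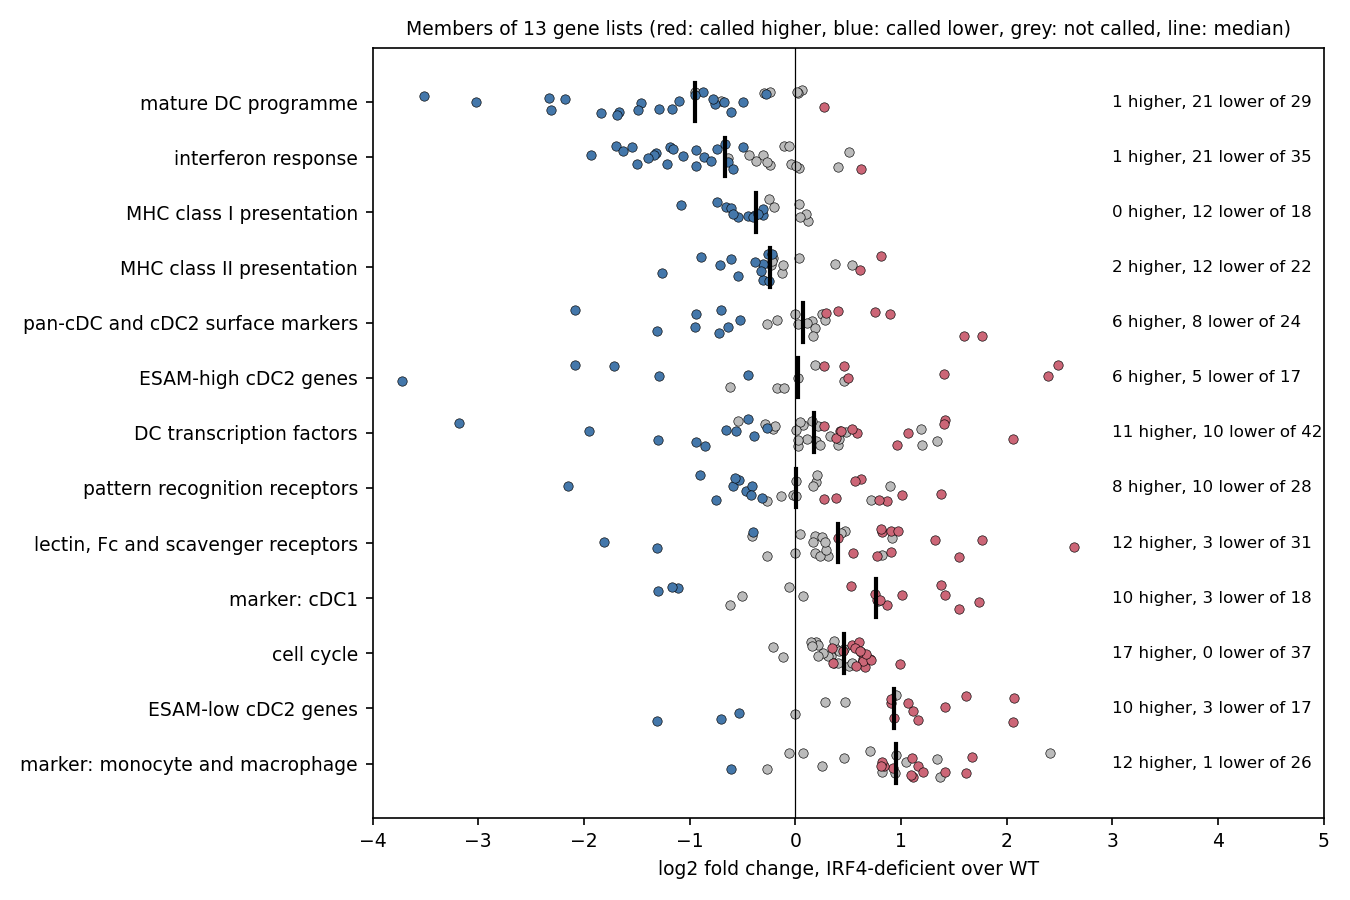
Log2 fold change of IRF4-deficient over WT (horizontal axis) for the tested members of 13 gene lists, 1 point per gene. Red points are called higher, blue points called lower and grey points not called, the black line is the list's median and the text gives the counts, from 21 of 29 lower in the mature dendritic cell programme to 12 of 26 higher among monocyte and macrophage markers.

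Genes were tested with edgeR's quasi-likelihood test and lists with camera, of which 11 of 32 tested lists passed, 7 up and 4 down. None of the 11 calls (0 of 32 lists) held when the correlation between genes was estimated from these libraries, where 2 lists had an unadjusted camera p under 0.05. The smallest unadjusted p of that camera version was 0.0268. With 4 residual degrees of freedom it had little power, so its failures do not separate correlated genes from too few libraries. The estimated correlations of the 11 lists ran from 0.047 (T cell) to 0.526 (cell cycle), all above the preset 0.01. If correlations are that high, the camera p-values with the preset correlation are too small. Fry, which asks whether a list's genes move on balance one way, passed 8. Of the 11 camera calls 5 passed fry and 6 did not, with fry adjusted p of 0.0534 for the ESAM-low list, 0.0537 for the monocyte list, 0.0917 for the lectin and the cell cycle lists, 0.0568 for the T cell list and 0.0534 for the erythroid and platelet list. The other 3 that passed fry, the IRF family, the apoptosis regulators and the mast cell, basophil and eosinophil markers, did not pass camera. The IRF family includes the deleted gene Irf4. The groups did not overlap for 4243 tested genes (35.6%, against 10% by chance with 3 libraries a group) and for 2350 of the 2429 called genes.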

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

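The Rn45s and Malat1 removal and the red pulp covariate were chosen after seeing the data. Irf4 was called lower under each alternative. Except under that covariate, the numbers of genes called, higher, lower and changed at least 2-fold stayed within 1.5 times the reported ones. Under DESeq2, limma-voom and the other scalings 2392 to 2492 genes were called, of which 2307 to 2415 were shared in direction with the reported calls. Leaving out 1 library gave 1779 to 2431 calls (868 to 1157 higher, 911 to 1274 lower, 761 to 948 at least 2-fold), an Irf4 log2 fold change of -2.05 to -1.82, and 9 to 13 lists past camera's threshold. With the covariate 867 genes were called, 405 higher and 462 lower, 542 at least 2-fold and 5 lists passed. The index values did not overlap between genotypes, at -0.06 to 0.86 in IRF4-deficient and -0.66 to -0.31 in WT libraries. The covariate therefore overlaps with the contrast itself and uses up 1 of 4 residual degrees of freedom. The share of the drop due to each was not tested. With an estimated correlation 0 lists passed, in a test with little power at 4 residual degrees of freedom. Its estimates exceeded the preset 0.01 for each of the 11 lists that passed camera in the main fit. The titles' replicate numbers, also used for the block, gave no sign of pairing the libraries, though 3 libraries a group cannot exclude a weak pairing. Over all pairs of an IRF4-deficient and a WT library, deviations from the group mean correlated at -0.04 to 0.051. Same-numbered libraries deviated with correlations of -0.005, 0.051 and -0.011, and not every library correlated best with its own number. With the replicate block 2267 genes were called (1090 higher, 1177 lower), 2187 of them shared in direction. Small changes may be missed, by a share that was not measured. The simulation recovered 32.8% of 1.5-fold changes, but with 154 calls its adjusted threshold was stricter than with the 2429 calls here. Of 64 counts of called list members, 4 with at least 5 calls and 16 with fewer moved by over 1.5 times when 1 library was left out, the 4 being class II lower, costimulation higher and cell cycle higher without WT replicate 2 and immediate early lower without WT replicate 3. The 16, with their ranges over those fits, were glycolysis higher (0 to 4), cholesterol higher (2 to 4) and lower (1 to 4), apoptosis higher (1 to 2), class II higher (1 to 3), interferon higher (1 to 3), mature programme higher (0 to 1), plasmacytoid lower (2 to 4), T cell higher (2 to 5), NK cell higher (1 to 2), B cell higher (0 to 1), plasma cell lower (0 to 1), neutrophil lower (0 to 2), erythroid and platelet lower (0 to 1), stromal and endothelial higher (0 to 1) and sex genes lower (0 to 1). The fits were compared for 202 genes, which include those named here but not every eligible list member. Of these, 22 lost their call without 1 library or another and 65 lost it with the covariate. Under the covariate Ctsl went to -0.003 on the log2 scale, a change of sign, and the cause was not tested. Of these 65, 16 kept under 0.5 of their log2 fold change, among them Irf1, Abca1, Mcl1, Lgmn, Clec9a, Ccr3, Csf3r, Vcam1, Clec12a, Fcgr3, Fn1 and Serpinb6a. The other 49 kept at least 0.5 of it, among them Cygb, Apof, Cd80, Cd274, Irf9, H2-Aa, Oas3, Klf2, Klf4, Tlr3, Snx22, Kit, Srebf2, Sdf2l1, Casp8, Cr2, Il7r, Ccr9, Cd14, Gbp7, Plcb2, Serpinb7, Mboat1, Xist and Malat1.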

Other observations

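The tests on residual Irf4, on macrophage genes, on cDC1 genes and on other splits of the libraries, and the gene families described next, were chosen after the results were seen, while the test of genes near Irf4 was written before. Several gene families that were not fixed beforehand, some with members in the fixed lists, held more than 1 strong change. Of 9 guanylate-binding protein genes, which act in interferon-induced defence against pathogens, 5 were called lower and 1 higher (Gbp7). Gbp4 fell from 198.2 ± 22.1 to 38.7 ± 3.98 CPM (n = 3 each) and Gbp9 from 317.1 ± 24.1 to 94.3 ± 17.2 CPM. All 3 paired immunoglobulin-like receptor genes were called higher, Pilra with a log2 fold change of 2.55 (SE 0.19), Pilrb1 with 2.25 (SE 0.16) and Pilrb2 with 2.32 (SE 0.14). Of 5 Ifitm genes 3 were called higher, among them Ifitm1 and Ifitm2 (log2 fold change 1.35, SE 0.15). In fits without 1 library 4 to 5 Gbp genes were called lower, 3 Pilr genes higher and 2 to 4 Ifitm genes higher. With the red pulp index as a covariate 4 Gbp genes were called lower and 0 higher, 3 Pilr genes higher, and 2 Ifitm genes higher and 1 lower.

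Of 10 killer cell lectin-like receptor genes 3 were called lower, led by Klri1, from 279.3 ± 15.9 to 32.1 ± 3.91 CPM, and Klri2, from 122.1 ± 2.14 to 44.1 ± 6.05 CPM. Of 9 Serpinb genes 4 were called lower (Serpinb2, Serpinb6b, Serpinb7 and Serpinb9) and 1 higher (Serpinb6a). Of 4 phospholipase C beta genes Plcb1 and Plcb4 were called higher, also in each fit without 1 library, and Plcb2 was called lower, but not without IRF4-deficient replicates 1 or 2 or WT replicates 2 or 3 (adjusted p 0.0981, 0.126, 0.071 and 0.116) or with the covariate (0.308). Of 5 Siglec genes 3 were called higher. In fits without 1 library 3 Klr genes and 4 to 5 Serpinb genes were called lower, and 1 to 2 Serpinb and 2 to 3 Siglec genes higher. With the covariate 3 Klr and 4 Serpinb genes were called lower, and 0 Serpinb genes and 1 Siglec gene higher. The 29 core histone genes and the 86 ribosomal protein genes had 0 calls by edgeR, DESeq2 and limma-voom, and 3 and 7 of them an unadjusted p under 0.05 by edgeR, while at most 1 gene of each was called without 1 library. The long noncoding RNA gene 9530059O14Rik (chromosome 9, 122572499 to 122679596) went from 48.6 ± 12.7 to 0.67 ± 0.517 CPM, or 1.4% of the WT level. Its log2 fold change ran from -6.87 to -5.82 in fits without 1 library.

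The first pattern is the 25.8% of the WT Irf4 level that remained. If undeleted cells with the average WT level of every gene made up the whole remainder, no gene could fall below that share. However, 11 genes had a remaining share under the lower 95% bound for Irf4 (one-sided normal approximation on edgeR's SE, adjusted p under 0.05). Among them were Adam8 at 9% of WT, Rasgrp3 at 10.4%, Klri1 at 11.5% and Ccr7 at 12.4%. That argues against undeleted cells with average WT expression as the whole source, though a smaller share of them is not excluded. It does not cover undeleted cells that differ from the WT average, such as those of a single subset. Reads from exons outside the deleted part cannot be told apart from undeleted cells by the remaining 25.8%, since counts per gene hold no exon resolution and the labels do not name the deleted exons.

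The second pattern is the higher level of macrophage and monocyte genes, for which a candidate source is RNA of red pulp macrophages in a sort whose gate the labels do not give. For the red pulp genes this stays open, since 10 of 12 index genes ordered the IRF4-deficient libraries alike, but the index was chosen after the libraries were seen to differ in these genes and any joint change of them would give a shared order. Emr1, a red pulp macrophage gene at 298 CPM in WT, was called lower, but bulk counts do not show which cells express it. For the 12 called monocyte and ESAM-low genes outside the index, the same RNA is unlikely to be the whole source, since their median log2 fold change was 1.18 (median SE 0.20) without and 0.85 (median SE 0.28) with the index as a covariate. Of these 12, Cx3cr1, Ccr2, Lyz2, Csf1r, S100a4 and Treml4 were still called. The others lost their call, among them Clec12a (0.91, then 0.20, SE 0.27), Csf3r (1.07, then 0.30, SE 0.34), Fcgr3 (0.90, then 0.35, SE 0.41), Cd14 (1.41, then 0.79, SE 0.51) and Fn1 (1.21, then 0.04, SE 0.67), through smaller folds, larger errors or both. Over all 17 alternatives Fn1 was past the threshold in 6 and Fcgr3 in 14. The evidence is therefore borderline, the index values did not overlap between genotypes, and the 12 genes were chosen because the same data called them higher. The index covers red pulp genes only, so RNA of other cells in the sort is not addressed. Whether loss of IRF4 acts within cDC2s or shifts their subsets also stays open and untested.

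The third pattern is the change in cDC1 genes. Of the markers 3 were called lower, Batf3, Wdfy4 and Snx22 (the last not with the red pulp index as a covariate), and no source of these decreases was tested. For the 10 markers called higher, RNA of cDC1s stays open: their log2 fold changes, 0.53 to 1.74 around a common value of 0.99, differed beyond their standard errors (Cochran's Q of 41 on 9 degrees of freedom, chi-square approximation that takes genes as independent, p = 5.09e-06), but differing levels of these genes in cDC2s would also do this. A direct change of these genes in cDC2s without IRF4 remains a hypothesis that bulk counts do not separate from it.

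The remaining tests gave no decision. Of 26 tested genes within 5 Mb of Irf4, 6 were called (23.1%, against 20.8% of 10732 elsewhere; odds ratio 1.14, 95% interval 0.38 to 2.96, one-sided Fisher's exact p = 0.463), so strain-linked differences around the floxed allele cannot be told apart from their absence with so few genes. The 6 were Serpinb9, Serpinb6b, Serpinb6a, Dusp22, Mboat1 and 1700011B04Rik. Of the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, called 2429 genes and the highest of the others called 0 by edgeR (at most 341 genes at an unadjusted p under 0.05, against 3789 for the real one), but 10 splits are too few for a share under 0.05.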
